A study of Mus musculus with 18 samples.

How the data were processed

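RNA was sequenced from MC3T3-E1 cells, a mouse preosteoblast line from newborn calvaria, that carried 1 of 3 lentiviral short hairpin constructs: the control shScramble, or shRcor2-18 or shRcor2-20, which were made to silence Rcor2, a corepressor of the CoREST family. Each construct was sampled at 0h, 24h and 7d, with 2 samples per group, so that 18 libraries fell into 9 groups. Per the labels' protocols, osteogenic medium held dexamethasone at 10 nM, ascorbic acid at 50 µg/ml and beta-glycerophosphate at 5 mM, and reads were 100 bp long. Group, time and sample number were taken from the sample titles. The titles give 0h where another label field gives the time in days, and the protocols name differentiation for 24 hours and until day 14 or day 21, with no mention of day 7, which the titles give, so the times are given here as the titles state them. Nothing in the labels says that the samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

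The authors deposited 1 table of raw read counts per gene for the whole series, which holds whole numbers that sum to between 2572026 and 9798498 per library. Reads were checked with FastQC and aligned with TopHat2 2.0.9 to mm9, per the submitters' processing notes, which also name DESeq and DESeq2. The counting program, its treatment of strand and of reads that match several places, and the annotation are not given in the sources used here. The table has 40620 rows with a gene identifier each, and 680 rows carry no symbol. Of the identifiers, 39632 (97.6%) were found in the reference annotation used here, GENCODE vM21 on GRCm38, and 98.0% of those had the same symbol there. The rows use gene identifiers of the GRCm38 period while the notes name mm9, so no coordinates are printed, and the annotation served only for names, gene types and gene order.

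Many genes that every cell uses held almost no counts. Each chromosome was therefore searched for a stretch from its start in which row names were in register with the reads. This step and its settings were chosen after the data were examined, and several settings were tried. Protein-coding genes in order along the chromosome were scored as detected at a mean of 20 CPM or more. An ordinary gene was taken to be detected with a chance of 0.6 in register and 0.4 out of it, and a gene from a hand-written list of commonly expressed genes with 0.9 and 0.4. The stretch with the highest log likelihood ratio was kept where it held at least 10 genes and a ratio of at least 3, and 3 genes were dropped at its far end. Families expressed in nearly all cells (ribosomal proteins, proteasome, respiratory chain and similar) were held out of the search and used to check it. The protein-coding genes of these stretches are called in-register genes. CPM of in-register genes are CPM relative to the total on the in-register genes tested, after TMM scaling.

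The planned test was edgeR 4.0.16 in R 4.3.3: filterByExpr over the 9 groups, TMM, robust dispersions, glmQLFit and glmQLFTest, with 9 group means, all rows and all 18 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. It left 12157 rows and 9 residual degrees of freedom. Standard errors are the log2 fold change divided by the square root of F. The knockdown was the mean of both hairpins minus shScramble, at each time and averaged over the times. Each hairpin alone, the hairpins against each other, and the change of the knockdown with time were tested as well. An added test, chosen after the data were examined, used the same model on the in-register genes and the 15 libraries other than sample 1 of each construct at 0h. It left 620 genes and 6 residual degrees of freedom, and each construct then had 1 library at 0h, which is assumed to vary like the other groups. The added comparisons of the times average over the 3 constructs. Deviations of libraries of the same construct and number correlated across genes at 0.30 to 0.57 between 24h and 7d in all 6 pairs. These libraries were therefore paired by construct and number. The 7d partner of another construct, given below, correlated at 0.37 to 0.55 with a 24h library, so the values do not single out this pairing. At 0h, deviations of same-numbered samples correlated at 0.83, 0.56 and 0.82 between the constructs, so there the number pairs the constructs. Both pairings come from the values, and the labels state none. A fit added afterwards therefore had the number within each construct as a replicate block beside the 9 group means, with 3 residual degrees of freedom.

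Genes to name were chosen by a rule fixed before the data were examined: per comparison the 8 largest rises and the 8 largest falls past the threshold, with a mean log2 CPM of at least 1 and no overlap between the libraries compared, without placeholder names, plus up to 4 members of each of 28 fixed gene lists with 570 entries. The rule was applied to in-register genes only, a restriction added afterwards. In the lists, 21 entries were in-register genes, 18 of them in 13 lists passed the filter, and the largest list had 3. The planned test of lists as sets (limma's camera) was therefore left out, since it needs at least 5 members here, and members are reported singly.

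The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The planned test at 24h recovered 0 of the 4-fold changes in the knockdown, in 1 hairpin alone or in the shScramble time comparison (11734 to 11771 rows), and 44 of 100 in the knockdown over all times (11760 rows), where it recovered 3 of 100 at 2-fold. The added test recovered 98 of 100 at 2-fold for 24h against 0h (613 genes), 100 of 100 for 7d against 24h (615 genes) and 91 of 100 for the knockdown at 24h (613 genes). Alternatives were other scalings, filters and tests (DESeq2 1.42.0, which ran on 26940 rows, or 784 in-register genes, with its own filter), only the groups compared, the sample number as a replicate block, and each library left out. No column of the table was left without a sample. No pair of libraries of the same time agreed within sampling noise, and pairs of different times were not compared in this way. Overlapping genes on opposite strands, among them Cyp51 and Akap9, Cnih2 and Yif1a, Iqcg and Lrch3, Rfc4 and Eif4a2, or Rtp4 and Masp1, cannot be told apart where strand was not used. Further such pairs are Cebpd and Spidr, Fosl1 and Ccdc85b, Crybg3 and Mina, Cdc45 and Ufd1l, and P3h2 and Gm4524. Adcy9 overlaps the pseudogene Gm6142 on the same strand, at a mean of 81.3 CPM of all counts each, so strand would not part them. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.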

Results

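The series addressed what silencing of Rcor2 does in MC3T3-E1 preosteoblasts as they differentiate. It held 18 RNA-seq libraries, 2 for each of 3 constructs (shScramble, shRcor2-18 and shRcor2-20) at each of 3 times (0h, 24h and 7d). Total counts ran from 2572026 to 9798498 per library, both of them at 0h. The totals were 3911277 to 6139315 at 24h and 3504808 to 4639679 at 7d. Between 11942 and 18277 rows had at least 1 count, and the 10 largest rows took 7.01% to 9.72% of the counts of a library.

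Many transcripts that every fibroblast or osteoblast makes were missing under their own names. Gapdh, the glycolytic enzyme, had a mean of 0.11 CPM over the 18 libraries, Vim, the intermediate filament vimentin, 0.17 CPM, and Col1a2, a chain of type I collagen, 0.58 CPM. Sparc, an abundant bone matrix protein, had 0.040 CPM, while Slc36a1, an amino acid transporter encoded near it, had 4091 CPM. Col3a1 had 0.099 CPM and its neighbour Col5a2 9745 CPM. Fth1, the ferritin heavy chain, had 0.88 CPM and the nearby Fads3 10500 CPM. Other such rows held some counts, with means of 66.0 CPM for Rplp0, 55.1 for Eef1a1, 24.3 for Actb and 23.0 for Col1a1. Among 697 members of broadly expressed families outside the stretches described next, 149 (21.4%) had 20 CPM or more, and their median was 0.60 CPM.

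Stretches from the starts of 7 of the 20 chromosomes (5, 8, 12, 16, 17, 18 and 19) were in register in the search. They held 36 members of the same families, 25 on chromosome 16, 8 on 19, 2 on 8 and 1 on 18, of which 34 (94.4%) reached 20 CPM, with a median of 271 CPM. The stretches of chromosomes 5, 12 and 17 held 0 members, so names there, among them Cyp51, Steap1 and Synj2, were not checked in this way. Chromosomes 8 and 18 gave a weak check, with only 2 members and 1. The log likelihood ratio of chromosome 8 was 3.48, the lowest kept, and 43 of its 79 genes scored were detected. Names there include F7, Mcf2l, Irs2, Ctxn1, Stxbp2 and Efnb2. The longest stretch covered 611 of the 646 protein-coding rows of chromosome 16, from Mefv to Cbr3. The stretch of chromosome 19 ran from Ighmbp2 to Gpha2 and held 134, and that of chromosome 8 ran from Insr to Erich1 and held 92. Together the stretches held 927 protein-coding rows and 18.4% of all counts. Only these in-register genes are named below. Elsewhere, a row is counted but its name is not taken as the gene its reads came from.

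**Figure D1:**
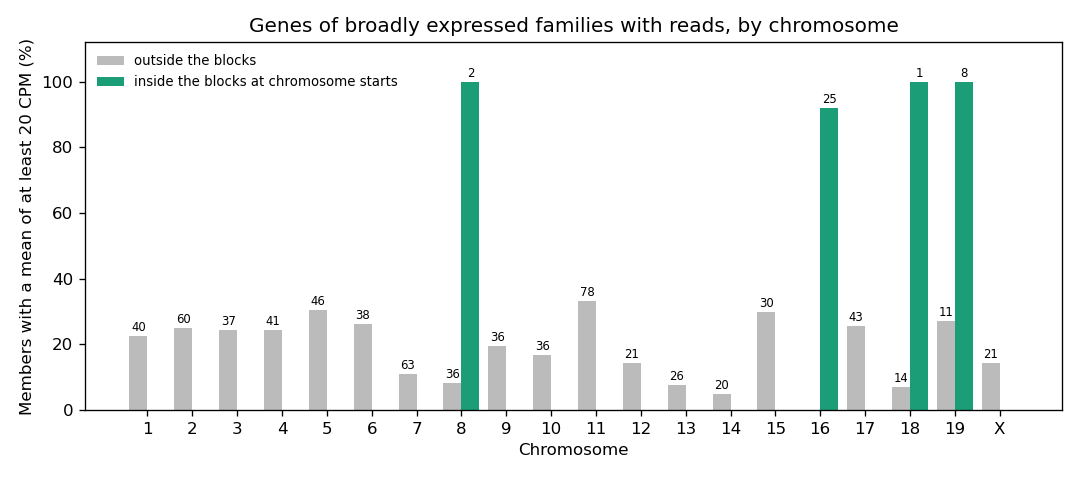
Share of broadly expressed family members with a mean of at least 20 CPM over the 18 libraries (vertical axis, percent), by chromosome (horizontal axis), inside (green) and outside (grey) the in-register stretches; the number above a bar is the number of members. Inside, 34 of 36 members passed; outside, 149 of 697 did.

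The row of the target, Rcor2 (ENSMUSG00000024968), held between 201 and 297 CPM in every library and was not detectably lower with either hairpin. Its mean at 0h was 235 ± 47.2 CPM with shScramble, 260 ± 52.0 with shRcor2-18 and 273 ± 11.4 with shRcor2-20 (SD, n = 2 each). At 24h the means were 231 ± 16.4, 220 ± 15.8 and 215 ± 1.66 CPM, and at 7d 212 ± 15, 211 ± 14.1 and 209 ± 7.66 CPM, in the same order. Over all times the hairpins differed from shScramble by 0.10 ± 0.11 on the log2 scale (SE; edgeR adjusted p = 1.00, unadjusted p = 0.40). At 0h the difference was 0.36 ± 0.20 (edgeR adjusted p = 1.00, unadjusted p = 0.0957), higher with the hairpins but not past the threshold. It was 0.34 ± 0.13 with 15 libraries (edgeR adjusted p = 0.643, unadjusted p = 0.0324) and 0.35 ± 0.097 with a term for sample 1 at 0h (edgeR adjusted p = 0.766, unadjusted p = 0.00410). At 24h it was -0.07 ± 0.19 and at 7d 0.01 ± 0.19. The row lies 35 coding genes past the end of the in-register stretch of chromosome 19, and the genes just before it, Otub1, Cox8a (a respiratory chain subunit) and Naa40, had means of 14.8, 3.95 and 14.2 CPM. Other coding neighbours held more, among them Mark2, the next gene (96.4 CPM), Stip1 (209 CPM) and Atl3 (268 CPM). Whether the row holds reads of Rcor2 is therefore not settled, and it does not check the construct labels. Libraries are named below by the label they carry.

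**Figure D2:**
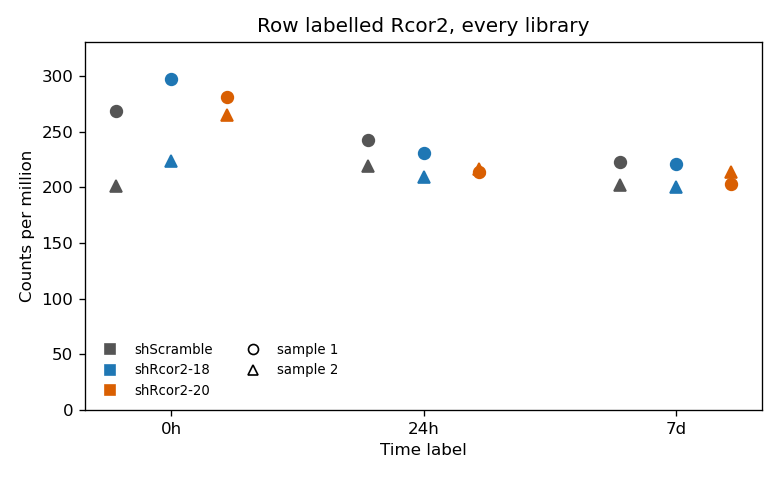
CPM on the row labelled Rcor2 (vertical axis) in each of the 18 libraries, by time label (horizontal axis), construct (colour) and sample number (marker). The values ran from 201 to 297 CPM, and libraries labelled with a hairpin overlapped those labelled shScramble at each time.

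Sample 1 of all 3 constructs at 0h stood apart from the other 15 libraries. Their log2 CPM over all rows correlated at 0.75 to 0.78 with the other libraries, which correlated with each other at 0.87 to 0.93, while the 3 correlated with each other at 0.99. Between 11942 and 14355 rows had counts in them, against 16555 to 18277 in the others, although the deepest library of the series was one of the 3. In-register genes took 25.2% to 25.8% of their counts, against 15.5% to 17% elsewhere. The added comparisons below leave these 3 libraries out.

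Over 532 in-register genes, none of the 18 libraries was closest to the other sample of its own construct and time. At 24h, sample 1 of shScramble was closest to sample 1 of shRcor2-18, sample 2 of shScramble to sample 1 of shRcor2-20, and sample 2 of shRcor2-18 to sample 2 of shRcor2-20. The same pairs held at 7d. The chi-square per degree of freedom was 3.47 to 9.36 within these pairs and 22 to 40.7 between the samples of 1 construct at those times. All were above 1, so no pair agreed within sampling noise. The comparisons of constructs below set libraries of such pairs against each other. The comparisons of the times below count both libraries of such a pair as independent. The n given there may therefore overstate the number of independent samples at 24h and 7d. It may do so at 0h as well, where the libraries used were all sample 2. Those of shRcor2-18 and shRcor2-20 at 0h stood at 4.29 from each other, and at 34.7 and 38.6 from shScramble. The SE and adjusted p of those comparisons rest on that n.

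**Figure D3:**
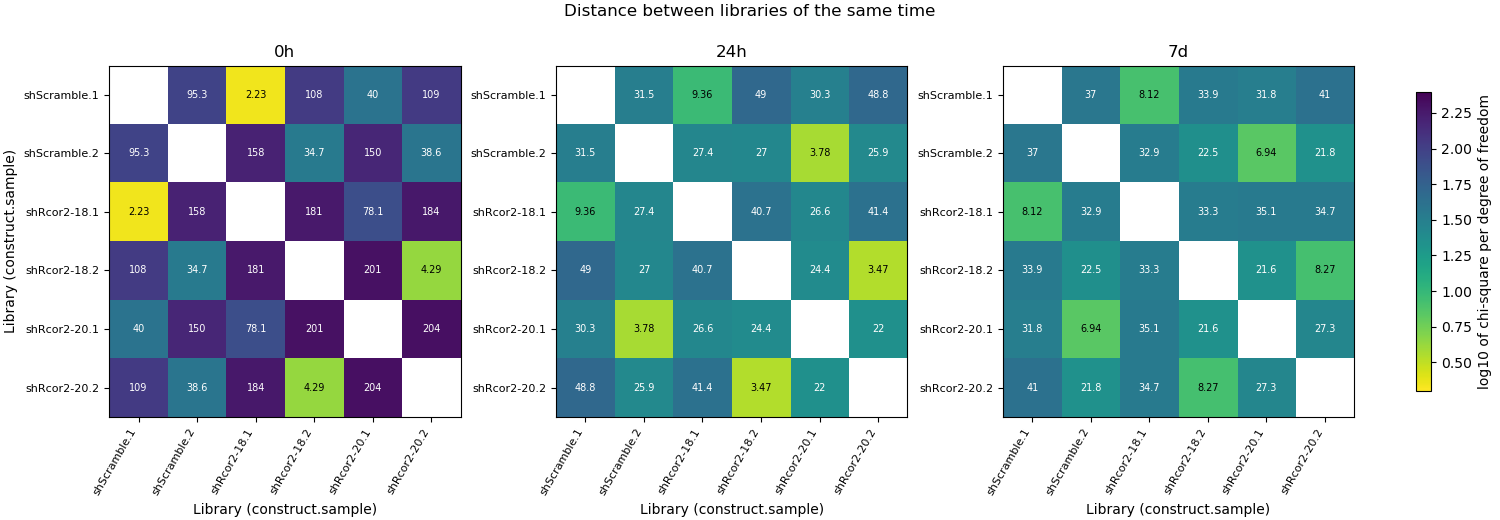
Distance between the 6 libraries of each time over 532 in-register genes, as the chi-square per degree of freedom of their counts (number in each square; colour is its log10), with construct and sample number on both axes. Light squares mark close libraries: at 24h and 7d each library has 1 partner of another construct at 3.47 to 9.36.

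At 24h against 0h, over the 3 constructs, 2 neighbouring genes for secreted proteases of the ADAMTS family changed in opposite directions. Adamts1, a metalloprotease that cleaves proteoglycans (ENSMUSG00000022893, chromosome 16), rose 6.41-fold, from 2462 ± 963 CPM at 0h (SD, n = 3) to 14966 ± 3306 CPM at 24h (n = 6), a log2 change of 2.68 ± 0.28 (SE; edgeR adjusted p = 0.000349), which ran from 2.30 to 3.36 over 19 other settings. Its neighbour Adamts5, an aggrecanase, fell by 0.96 ± 0.13 on the log2 scale (adjusted p = 0.00121). Cebpd, a transcription factor that glucocorticoids induce, rose 2.58-fold, from 408 ± 37.7 to 1054 ± 121 CPM. Lrp5, a Wnt coreceptor needed for bone mass, rose 2.59-fold, from 5382 ± 1183 to 13707 ± 476 CPM. Hes1, the transcriptional repressor that Notch signalling induces (ENSMUSG00000022528, chromosome 16), fell 11.1-fold, from 155 ± 17 to 14.9 ± 7.04 CPM (log2 change -3.48 ± 0.31; adjusted p = 7.99e-05).

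Other large rises at 24h were those of F7 (coagulation factor VII; log2 change 4.05 ± 0.53), Actn3 (the alpha-actinin of fast muscle fibres; 4.05 ± 0.35), Mcf2l (a guanine nucleotide exchange factor; 3.02 ± 0.23), Pla1a (a phospholipase; 1.84 ± 0.36) and St6gal1 (a sialyltransferase; 1.67 ± 0.42). F7 and Mcf2l are neighbours on chromosome 8, and F7 had only 2.41 ± 0.74 CPM at 0h. Further falls were those of Irs2, an insulin receptor substrate (-1.56 ± 0.33), Pkp2, a plakophilin of desmosomes (-1.31 ± 0.24), Lrrc15 (-1.22 ± 0.23), Ccdc80, a matrix protein (-1.06 ± 0.19), Tnk2, a tyrosine kinase (-1.0 ± 0.14), and Etv5, an ETS transcription factor (-0.88 ± 0.15). Each of these genes separated all 6 libraries at 24h from all 3 at 0h, which the rule for naming genes required. In all, edgeR called 15 of 620 in-register genes higher and 20 lower (DESeq2: 24 and 27). Without sample 2 of shScramble at 0h, Actn3 stood at 3.29. With the 3 libraries of sample 1 at 0h included, 69 genes were called. With all rows of the 15 libraries tested together, 17 in-register genes were called at 24h, 74 at 7d against 0h and 30 from 24h to 7d. Irs2 and St6gal1 lost their calls in 6 and 10 of 19 other settings.

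By 7d the largest rises were those of Apod and F7, whose order is not settled. Apod, a lipocalin that carries lipids, rose 54.8-fold, from 48.0 ± 20.5 CPM at 0h (SD, n = 3) to 2553 ± 1480 CPM at 7d (n = 6; log2 change 5.78 ± 0.79, edgeR adjusted p = 0.00101). The log2 change ran from 5.30 to 7.02 over 19 other settings, the highest with all 18 libraries. F7 rose by 5.71 ± 0.51, Actn3 by 4.67 ± 0.36, Btla, an inhibitory receptor of lymphocytes, by 4.08 ± 0.67, Adamts1 by 3.16 ± 0.29, Mcf2l by 2.82 ± 0.22 and Abat, the enzyme that breaks down GABA, by 2.53 ± 0.31. Fbxo40, a muscle F-box protein, rose by 2.35 ± 0.74 (adjusted p = 0.0421), a call lost in 11 of 19 other settings. Pkp2 fell 8.88-fold, from 230 ± 34.1 to 25.8 ± 9.01 CPM (-3.15 ± 0.26, adjusted p = 2.26e-05). Hes1 stood at 20.4 ± 7.37 CPM (-2.92 ± 0.30). Cst6, a cystatin, fell by 2.46 ± 0.65, Lrrc15 by 2.42 ± 0.23, P3h2, a collagen prolyl hydroxylase, by 2.16 ± 0.39, Synj2, an inositol phosphatase, by 1.99 ± 0.15, Alcam, an adhesion molecule, by 1.79 ± 0.42, and Cnih2 by 1.68 ± 0.24. EdgeR called 81 of 620 genes higher and 88 lower (DESeq2: 86 and 90), and 104 genes in all without sample 2 of shScramble at 0h, where Actn3 stood at 3.91. Without sample 1 of shRcor2-18 at 7d, Cst6 stood at -3.08. Of the genes called at 24h, 14 of 15 that rose and 19 of 20 that fell were also called at 7d, where independent lists would share 1.96 and 2.84; both comparisons use the same 0h libraries.

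From 24h to 7d, with 6 libraries each and no 0h library involved, Apod rose by a further 4.17 ± 0.51 on the log2 scale, Btla by 2.51 ± 0.44, Abat by 2.20 ± 0.23 and F7 by 1.67 ± 0.26. Crybg3 rose by 1.54 ± 0.15, Ctxn1 by 1.28 ± 0.19, Tmem44 by 1.22 ± 0.13, and Fam162a, a mitochondrial protein that hypoxia induces, by 1.12 ± 0.22. Cyp51, the lanosterol demethylase of cholesterol synthesis, fell 2.06-fold, from 6511 ± 1801 to 3127 ± 345 CPM (edgeR adjusted p = 0.00183). Pkp2 fell by 1.84 ± 0.23, Synj2 by 1.34 ± 0.13, Lrrc15 by 1.20 ± 0.21 and Arhgap31, a GTPase-activating protein, by 0.96 ± 0.10. Cst6 (-2.39 ± 0.57) and P3h2 (-1.43 ± 0.34) lost their calls in 7 and 8 of 21 other settings, and Cst6 stood at -3.00 without sample 1 of shRcor2-18 at 7d. Iqcg fell by 1.99 ± 0.41, at levels of 9.83 ± 4.13 and 2.21 ± 1.06 CPM. EdgeR called 55 of 620 genes higher and 54 lower (DESeq2: 68 and 73), or 69 and 45 with library size as the only scaling. With the number within each construct as a replicate block, which pairs the libraries of 24h and 7d, it called 94 higher and 97 lower, among them all 109. The count of 109 fell to 51 without sample 1 of shRcor2-20 at 24h, to 62 without sample 2 of shRcor2-18 at 7d, to 64 and 67 without sample 2 or 1 of shScramble at 24h, to 71 without sample 2 of shRcor2-20 at 7d, and to 72 without sample 2 of shRcor2-20 at 24h.

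**Figure D4:**
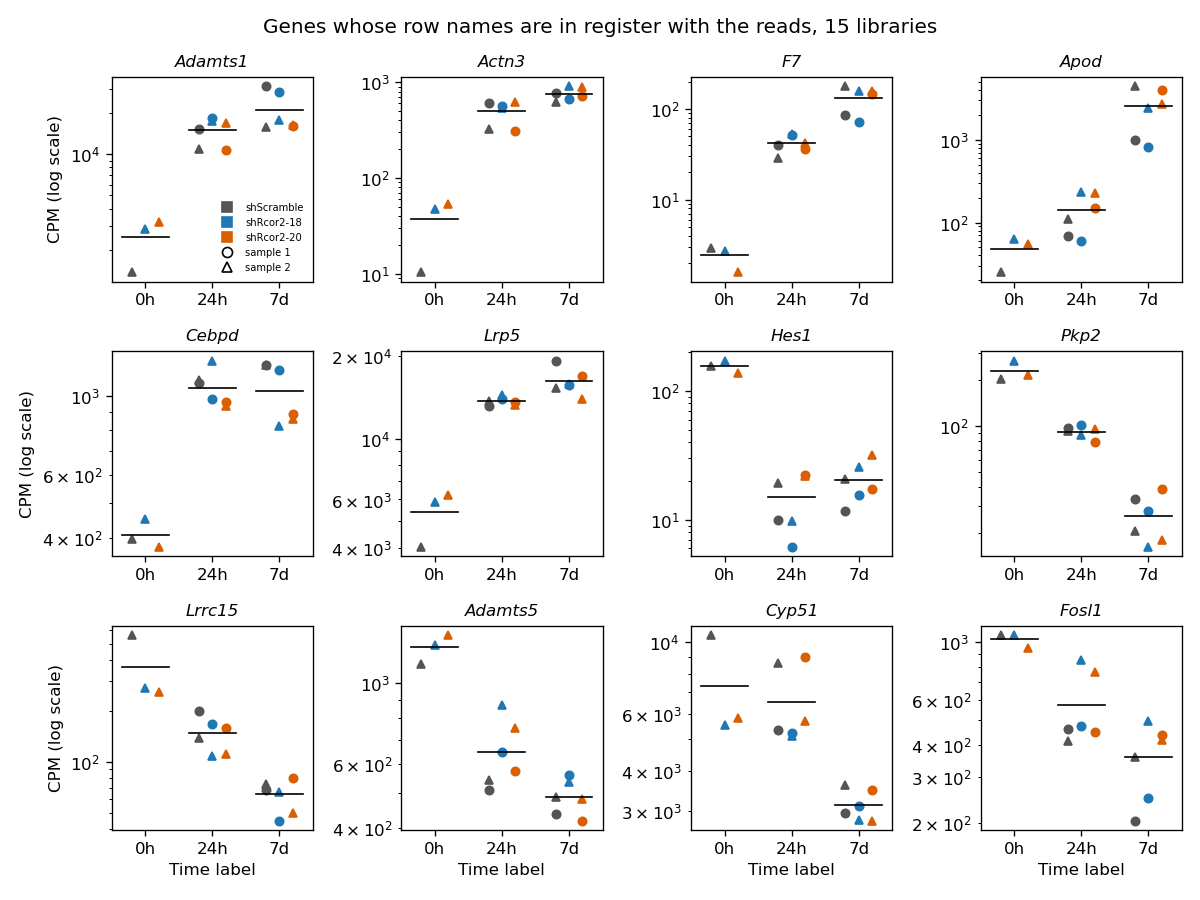
CPM of in-register counts (vertical axes, log scale) of 12 in-register genes at 0h, 24h and 7d in 15 libraries, with construct as colour, sample number as marker and the mean as a line. Adamts1, Actn3, F7, Cebpd and Lrp5 were higher in all 6 libraries at 24h than in all 3 at 0h, Hes1, Pkp2, Lrrc15 and Adamts5 were lower, and Apod was higher in all 6 libraries at 7d than at the other times. The rule for naming genes required such separation, so it is no separate result.

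Among the 28 gene lists fixed beforehand, 18 members in 13 lists could be tested. Most of these lists had only 1 member tested, whose p adjusted over the list alone is its unadjusted p. At 7d against 0h, 2 of them rose and 6 fell past the threshold over all 620 genes (3 and 8 when adjusted over the list alone). Of 3 DNA replication genes, the helicase subunit Mcm4 fell by 0.90 ± 0.26 (edgeR adjusted p = 0.0309), while Cdc45 (-0.67 ± 0.27) and Rfc4 (-0.47 ± 0.23) did not pass. Fosl1, an immediate early transcription factor, fell by 1.53 ± 0.28 and Cyp51 by 1.16 ± 0.17. Snai2, a zinc finger repressor found with CoREST, fell by 0.80 ± 0.25 (adjusted p = 0.0405). Of the BMP antagonists, Chrd stood at 0.63 ± 0.23 and Bambi at -0.59 ± 0.34, neither past the threshold. At 24h against 0h, 2 members rose and 2 fell (2 and 4 when adjusted over the list alone), and from 24h to 7d 0 rose and 2 fell (3 and 5 when adjusted over the list alone; 9 members had an unadjusted p under 0.05). With the replicate block, 4 rose and 6 fell from 24h to 7d. The 8 members that passed only with it were Adamts1 (0.46 ± 0.11), Chrd (0.56 ± 0.16), Npas4 (0.72 ± 0.21), Sdf2l1 (0.37 ± 0.11), Bambi (-0.68 ± 0.19), Mcm4 (-0.50 ± 0.085), Fosl1 (-0.67 ± 0.15) and Rtp4 (-0.83 ± 0.20).

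With shScramble alone and all 18 libraries, as planned, edgeR called 4 of 12157 rows higher and 0 lower at 24h (614 rows at an unadjusted p under 0.05; DESeq2: 89 and 21). The in-register row among the 4 was Adamts1 (3.39 ± 0.46, adjusted p = 0.0437), and the names of the other 3 rows are not taken as genes. At 7d edgeR called 14 rows higher and 3 lower (DESeq2: 183 and 118), or 18 and 7 with RLE size factors and 13 and 5 with library size only. The in-register rows were Adamts1 (4.26 ± 0.48, adjusted p = 0.00865) and Actn3 (4.41 ± 0.70, adjusted p = 0.0437). These calls were lost in 8 of 16 other settings for Adamts1 at 24h, in 4 for Adamts1 at 7d and in 5 for Actn3, which stood at 6.10 without sample 1 of shScramble at 0h and 3.60 without its sample 2. The median row differed from 0h by 0.19 and 0.14 on the log2 scale at the 2 times. Leaving out 1 shScramble library left 0 or 1 row at 24h, and at 7d 5, 1, 1 and 3 rows without sample 1 at 0h, sample 2 at 0h, sample 1 at 7d and sample 2 at 7d. In the added test, shScramble alone gave 7 genes higher and 3 lower at 24h, and 30 higher and 34 lower at 7d (DESeq2: 13 and 6, and 42 and 46). Among the 7 were Adcy9, an adenylate cyclase (1.61 ± 0.33), and Cblb, a ubiquitin ligase (1.17 ± 0.19), which lost their calls in 3 and 2 of 9 other settings. Among the 34 were Steap1 (-1.76 ± 0.38) and Tprg (-1.98 ± 0.49), each lost in 3 of 9, and Stxbp2 (-2.67 ± 0.75), lost in 8 of 8. Without sample 1 of shScramble at 24h, 3 genes were called at 24h, and without its sample 1 at 7d, 38 were called at 7d.

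In the tests run, adjusted over all genes tested, no in-register gene differed detectably between libraries labelled with hairpins against Rcor2 and those labelled shScramble. No fit had all the partners above as blocks; the sample number joins shScramble sample 1 with shRcor2-18 sample 1, and the crossed pairing shScramble sample 2 with shRcor2-20 sample 1. For the genes that moved with time, the differences over all times were 0.37 ± 0.20 for Adamts1, 0.12 ± 0.27 for Hes1, -0.14 ± 0.11 for Cebpd and 0.30 ± 0.21 for Snai2 on the log2 scale. The lowest unadjusted p among list members was that of Cyp51 (-0.39 ± 0.14; edgeR adjusted p = 0.576 over 620 genes and 0.0218 when adjusted over the list alone, where it is the only member). Bambi, a decoy receptor of BMP signalling, stood at 0.76 ± 0.29 over all times and 1.10 ± 0.47 at 7d, with adjusted p of 0.576 and 0.996. At 24h 1 member passed when adjusted over the list alone, Adamts5 (0.43 ± 0.16), and at 7d also 1, Cebpd (-0.38 ± 0.15), against 0 over all genes. Cebpd was the only member of its list tested, so its p there is unadjusted.

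Over the 620 in-register genes, edgeR and DESeq2 called 0 genes in the knockdown at 0h, at 24h, at 7d and over all times. The genes at an unadjusted p under 0.05 in edgeR numbered 62, 6, 9 and 49. The median size of the difference was 0.25, 0.11, 0.11 and 0.12 on the log2 scale, with a median SE of 0.25, 0.18, 0.18 and 0.12, and 90% of genes lay within 0.78, 0.40, 0.39 and 0.33. The change of the knockdown from 0h to 24h and to 7d gave 0 genes in both tools, with 38 and 27 at an unadjusted p under 0.05. The hairpins against each other also gave 0 genes in both tools at 0h, 24h and 7d (2, 6 and 3 genes at an unadjusted p under 0.05). With the sample number as a replicate block, edgeR called 0 genes in the knockdown at 0h, 24h and 7d and over all times (89, 16, 12 and 75 unadjusted). The crossed pairing gave 0 for shRcor2-20 at 24h and 7d (18 and 10 unadjusted). The spread in these tests includes the differences between the samples of 1 construct given above.

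In the planned test of 12157 rows, edgeR called 0 rows in the knockdown at 0h, 24h and 7d and over all times, with 235, 160, 188 and 228 rows at an unadjusted p under 0.05, where DESeq2 called 18, 18, 3 and 14. The same test called 0 rows for shRcor2-18 at the 3 times (159, 134 and 156 rows unadjusted; DESeq2: 3, 13 and 5) and 0 for shRcor2-20 (220, 180 and 154 rows; DESeq2: 15, 10 and 1). No row passed for both hairpins in edgeR, and 59, 40 and 44 rows had an unadjusted p under 0.05 in the same direction with both (DESeq2: 2, 5 and 1 rows past the threshold). The hairpins against each other gave 0 rows (175, 174 and 159 unadjusted; DESeq2: 16, 6 and 5), as did the change of the knockdown to 24h and 7d (165 and 189 rows unadjusted; DESeq2: 13 and 13). At 0h the sample number pairs the constructs, and with it as a replicate block edgeR called 7 rows in the knockdown at 0h, 4 over all times, and 6 and 12 for its change. It called 1 for shRcor2-18 at 0h, 7 for shRcor2-20 and 7 for the hairpins against each other, none of them in-register genes. With 44 of 100 simulated 4-fold changes recovered over all times and 0 at 24h, changes of that size could be missed in this test.

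The log2 differences of the 2 hairpins from shScramble correlated across 12157 rows at 0.54, 0.45 and 0.52 at 0h, 24h and 7d. With 1 library left out, these correlations ran from 0.32 to 0.83, 0.33 to 0.63 and 0.39 to 0.70. In 10 simulations, all libraries, shScramble included, were drawn independently from 1 mean per row and time, without partners. These simulations gave means of 0.53, 0.49 and 0.51. The observed value lay within their range at 0h and 7d and below it (0.47 to 0.51) at 24h. The covariance was 1.5, 0.96 and 1.22, against 1.39, 1.29 and 1.38 in the simulations. Over the 620 in-register genes the correlations were 0.68, 0.54 and 0.56, within the range of the simulations at each time (0.39 to 0.74, 0.30 to 0.63 and 0.17 to 0.65). Their covariances were 0.35, 0.13 and 0.17, against 0.21, 0.071 and 0.086 in the simulations. The share of genes with the same sign for both hairpins at 0h was 86.3%, above the simulated range (64.2% to 71.3%), and 72.5% over all rows (66.2% to 67.6%). It was 68.1% and 67.6% of in-register genes at 24h and 7d, within the ranges, while over all rows it was 65.4% at 24h, below the range (65.9% to 67.0%), and 66.3% at 7d, within it. Genes are not independent replicates. Both hairpins were set against the same control libraries, 2 of them, or 1 at 0h for in-register genes. The controls were not split between the hairpins. Part of any excess may therefore come from the controls. For in-register genes at 0h, the hairpin libraries were close to each other (chi-square per degree of freedom 4.29) and far from shScramble (34.7 and 38.6). The simulations hold no such pairing, so values outside their range are not taken as an effect of the hairpins.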

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

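The tests of the 3 patterns below were chosen after the results were seen; the counts of other splits were planned before their results, apart from the 32 splits of pairs. Chance flags about 1 in 20 groups: of 109 groups of 6 libraries searched for a library far from the others, 2 were found, where 5.45 would be expected. Etv5 at 7d was highest in sample 2 of shRcor2-18, at 241 CPM against a median of 167 CPM in the other 5, a gap of 0.69 of the whole range. Sdf2l1, an endoplasmic reticulum protein, was highest at 7d in sample 1 of shRcor2-18, at 461 against 432 CPM, a gap of 0.67 of the range.

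Many genes of every cell had almost no counts under their own names on most chromosomes. Among the held-out family members, 21.4% were detected outside the in-register stretches, against 94.4% inside. Too few reads are argued against, since members inside had a median of 271 CPM in the same libraries. Names shuffled over the whole table are argued against too: a shuffle would leave 8.99 of the 36 inside detected, and 34 were. A candidate explanation that the values leave open is that reads were counted at positions of 1 genome build and named from another, which would keep names in register from a chromosome's start to a point that differs by chromosome (611 of 646 coding rows on chromosome 16); no biological explanation was tested.

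The 3 libraries of sample 1 at 0h stood apart from the other 15. Shallower sequencing is argued against, because the shallowest and the deepest library were both among them, and even the deepest had counts in only 14355 rows, fewer than any library outside the 3. A state of the cells is argued against as the whole cause: of coding rows with at least 20 CPM in sample 2 at 0h, 15.3% outside the in-register stretches were over 16-fold lower in sample 1, but 0 of 523 inside, and 0 of 413 on chromosomes 16 and 19, where families checked the names. Reads that match several places may have been treated in another way, at least for pseudogene rows, which had at most 101 counts per 1000 in-register coding counts in these libraries and at least 240 elsewhere. Whether this also covers the coding rows outside stays open, since the source of their reads is unknown. In-register genes also differed between samples 1 and 2 at 0h. Their chi-square per degree of freedom between the samples of 1 construct was 95.3 to 204, against 22 to 40.7 at 24h and 7d. A state of the cells therefore stays open as part of the cause.

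All 12 libraries at 24h and 7d were closest to a library of another construct, which 8 of the 15 ways to pair 6 libraries would also give, so this count does not speak for exchanged labels. Handling at 1 time alone is argued against. Across genes, the deviation of a 24h library from its time mean correlated with that of its 7d partner at 0.37 or more. Libraries of 1 construct and other numbers stayed at -0.01 or below. Taking deviations from the mean of a time by itself pushes such values down, so they are no independent contrast. All 6 samples had the same partner at 24h and 7d, and deviations of the same construct and number correlated at 0.30 to 0.57. Exchanged construct labels and cultures kept in parallel through both times, with the labels right, cannot be told apart. The row of Rcor2 lies past the in-register stretch, so it checks neither. Handling of the same pairs together at both times was not tested and stays possible as well. A biological effect of the hairpins stays untested by this.

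Other splits of the libraries were counted for the comparisons with at least 3 libraries on each side. For 7d against 24h, 1 of 100 splits, the real one, gave as many genes (156 in a model of the 2 times alone; highest other 12). With construct and number taken as pairs, 32 splits part all 6 pairs. Of these, 1, the real one, gave as many genes (218 with the pairs as a block, highest other 0). For 24h against 0h the count was 1 of 84 (59 genes, highest other 17). For 7d against 0h it was 1 of 84 (195 genes, highest other 3). These splits take libraries, or pairs of construct and number, as independent. Libraries had partners of another construct at 24h and 7d, and those used at 0h were all sample 2. The counts therefore show that the calls follow the times, but cannot exclude chance differences between sets of libraries. For the knockdown over all times, 40 of 40 splits gave as many rows as the real 0, which any split must, so this count says nothing about chance. The highest other split called 773 rows, and 6 of 39 called 10 or more. What made these splits call rows was not tested. In the highest, the controls were samples 1 of shRcor2-18 and shRcor2-20 at 0h, sample 1 of shScramble and its partner at 24h, and samples 2 of shScramble and shRcor2-20 at 7d, which are not partners.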

How the results depend on the processing

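Apart from the in-register genes, the 15 libraries, the term for sample 1 at 0h, the crossed pairing, and the number within each construct or at 0h as a block, which were chosen after the data were examined, the settings were fixed beforehand. Of the counts and correlations under other settings, 528 stayed close to the value reported and 132 moved. Counts of 0 that stayed at 0 are among the 528, so this number does not measure how steady the other counts were. For the 77 gene results picked as largest rises and falls, 1109 values kept their side of the threshold, 115 lost it and 0 reversed. Members named only from the lists are not in these counts, and among them Npas4 turned direction with a replicate block, as given below. Of 74 gene results in the 15-library test, 45 were past the threshold in every setting run, and all 3 of the 18-library test lost it in at least 1. Of all 77, 20 moved by over 1.5 times in at least 1 setting. The cause of the moves below was not tested, except where fewer libraries or genes entered. The Rcor2 row stayed between 0.03 and 0.17 over all times. The planned list tests were not run, since no list had 5 members tested. The planned test recovered 0 of 100 simulated 4-fold changes in the knockdown at 24h, and the added test 100 of 100 with the same libraries at 24h, and the cause of this gap was not tested.

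With DESeq2 on all rows, the knockdown gave 18, 18 and 3 rows at 0h, 24h and 7d, 14 over all times, and 13 and 13 for its change to 24h and 7d. The counts were 3, 13 and 5 for shRcor2-18, 15, 10 and 1 for shRcor2-20, 2, 5 and 1 for both hairpins, and 16, 6 and 5 for the hairpins against each other. ShScramble alone gave 110 rows at 24h and 301 at 7d, and 19 in-register genes at 24h.

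With 15 libraries and all rows, edgeR called 20, 2 and 5 rows in the knockdown at 0h, 24h and 7d, 1 over all times, and 12 and 18 for its change. It called 14, 5 and 9 for shRcor2-18, 22, 2 and 5 for shRcor2-20, 3, 2 and 5 for both hairpins, and 31, 2 and 4 for the hairpins against each other. ShScramble alone gave 48 and 124 rows. With a term for sample 1 at 0h, the knockdown gave 7, 2 and 6 rows, 4 over all times, and 6 and 12 for its change. ShRcor2-18 gave 1, 2 and 7, shRcor2-20 7, 2 and 5, both hairpins 2 at 24h and 5 at 7d, and the hairpins against each other 7 at 0h and 2 at 7d. ShScramble alone gave 62 and 209 rows, and the correlation of the hairpins at 0h was 0.61.

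For shScramble alone at 24h, RLE size factors gave 2 rows, library size only 2, no filter 9 and in-register genes with 18 libraries 13. At 7d, no filter gave 36 rows and in-register genes with 18 libraries 54. With only the groups compared, both times gave 0 rows, the knockdown at 24h 2 and shRcor2-18 at 24h 1. In-register genes of shScramble at 7d numbered 42 without a filter and 40 with the stricter one, under which the correlation of the hairpins at 24h was 0.41. Over all constructs, 18 libraries gave 69 genes for 24h against 0h and 72 for 7d against 24h. All rows of the 15 libraries gave 240 for 24h against 0h, 745 for 7d against 0h and 302 for 7d against 24h, of which 17, 74 and 30 were in-register genes, where the test of in-register genes alone called 35, 169 and 109.

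With the sample number as a replicate block, shScramble at 7d gave 30 rows; this block moved no other count of calls by over 1.5 times. Deviations of same-numbered samples correlated across genes at 0.60, -0.17 and 0.44 at 24h, and 0.34, -0.15 and 0.20 at 7d. The values are for shScramble with shRcor2-18, shScramble with shRcor2-20, and shRcor2-18 with shRcor2-20, in this order. The numbers therefore do not pair shScramble with shRcor2-20 at these times, and so do not pair all constructs. At 0h they do, and with the number at 0h as a replicate block the knockdown gave 7 rows at 0h, 4 over all times, and 6 and 12 for its change, shRcor2-18 1, shRcor2-20 7 and the hairpins against each other 7, but 0 genes in each when in-register genes were tested alone. ShScramble alone then gave 2371 rows at 24h and 2811 at 7d, or 55 and 116 in-register genes, and all constructs with 18 libraries 178 and 291 genes. These time counts set the later libraries against the mean of both samples at 0h, which differ strongly, and are not taken as effects of time. The crossed pairing of shRcor2-20 with shScramble gave 0 rows at each time. With the number within each construct as a replicate block, which pairs the libraries of 24h and 7d, 191 genes were called for 7d against 24h, where the test without it called 109. All 109 were kept, and apart from the 82 gained the block changed no other call there. The same fit called 62 genes for 24h against 0h (34 of the 35 kept, 28 gained) and 202 for 7d against 0h (158 of the 169 kept, 11 lost, 44 gained). At 7d against 0h, Efnb2 (-0.56 ± 0.18), Cdc45 (-0.51 ± 0.16) and Npas4 (-0.82 ± 0.28, without it 0.06 ± 0.58) passed only with it, and at 24h Efnb2 (-0.73 ± 0.18), Npas4 (-1.53 ± 0.28) and Snai2 (-0.36 ± 0.10). No pairing with 0h was checked, since 1 library per construct was left there.

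Leaving out 1 library at a time, the counts ran from 0 to 1 for the hairpins against each other at 0h, 0 to 4 for the knockdown at 0h and 0 to 1 for shRcor2-18 at 0h. ShScramble alone gave 0 to 1 rows at 24h and 1 to 5 at 7d, and 3 to 8 and 38 to 51 in-register genes. Over all constructs, 7d against 0h gave 104 to 155 genes and 7d against 24h 51 to 99. The correlation of the hairpins ran from 0.32 to 0.83 at 0h, 0.33 to 0.63 at 24h and 0.39 to 0.70 at 7d. Where an arm was left with 1 library, it was assumed to vary like the other groups.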

Other observations

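The values here were picked after they were seen, apart from the gene lists, which were fixed beforehand. Several list members did not pass the threshold in edgeR, which does not show that they kept their level. Efnb2, an ephrin, stood at -0.90 ± 0.53 on the log2 scale at 7d against 0h, Parp14 at -0.45 ± 0.28, the neuronal factor Npas4 at 0.06 ± 0.58 and the smooth muscle myosin Myh11 at -0.78 ± 0.27. With the number within each construct as a replicate block, Efnb2 stood at -0.56 ± 0.18 and Npas4 at -0.82 ± 0.28, a turned direction, and both passed, though no pairing with 0h was checked. From 24h to 7d, Rtp4, an interferon-induced gene, stood at -0.91 ± 0.31 (edgeR adjusted p = 0.0699), and at -0.83 ± 0.20 (edgeR adjusted p = 0.00860) with that block.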
